A study of Mus musculus with 6 samples.

How the data were processed

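RNA of 6 cultures of primary mouse aortic endothelial cells was measured on Affymetrix GeneChip mouse genome arrays, 3 from non-transgenic mice and 3 from mice with an endothelial, dominant negative human PPARG. Per the labels' protocols, the cells of 10 mice per group were grown as 5 cultures of 2 mice each, 3 cultures per group were arrayed, and about 50 ng of total RNA went through a two-step amplification before hybridization. Where RNA is degraded or amplification starts at the 3' end of transcripts, the signal of probe sets far from that end can be lowered, so the 3' to 5' ratios of the control probe sets were computed for each array. Groups and replicate numbers were taken from the sample titles.

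The authors deposited one intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. Its version is not given in the sources used here. The MAS5 algorithm in general combines the perfect match and mismatch probes of a probe set and scales each array to a target. The deposited intensities ran from 0.1 to 67821.8, and the mean without the lowest and highest 2% of probe sets was near 1500 on every array, so the scaling was kept. Detection calls were not used here. No 2 arrays shared more than 0.142% of their values exactly, so no array was a copy of another. The table held 45101 probe sets, of which 64 were array controls.

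Gene names came from the array annotation as given, in which 34945 probe sets had 1 gene, 932 had several and were not named, and 9160 had none listed. Symbols were updated by gene identifier for 34741 probe sets with RefSeq's mouse gene table, assembly GRCm38.p6, which was used for names and gene type alone. No coordinates are given, since neither the table nor the labels name a genome build.

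Values were computed as log2(intensity + 16). Each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays, and 11208 genes were tested whose mean reached the median of all probe sets that are not controls, a log2 value of 7.717 (a signal of 194). The difference between the groups was tested two-sided in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a trend on mean level) and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) given with differences are limma's moderated ones, over 3 cultures per group. Gene lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. camera compares the genes of a list with all other tested genes, while fry's directional p asks whether the list's genes move on balance one way. Single quality values were compared by exact permutation, and shares of genes by Fisher's exact test.

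The test, the filter, the gene lists, the rule for the genes named and most alternatives were chosen before the data were examined. The rule takes, per direction, 10 genes past the threshold with the largest difference, or where fewer exist those with the smallest unadjusted p, and adds Pparg, Fabp4, Rbp7, Cdh5, Pecam1, Nos3, the sex-linked genes and the members of each list with the smallest p, at least 2 per list. Lymphatic endothelial markers, with 4 genes above the filter, and the sex-linked genes were not tested as lists. The alternatives were other pseudocounts, filters, scalings, variance priors and array weights, other ways to combine the probe sets of a gene, the replicate number as a block, each array left out in turn, and the other list tests. Fits with the 3' to 5' ratio of the beta-actin or the Gapdh control probe sets as a covariate were added after seeing the data.

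The test was checked on simulated data for 11208 genes, each with limma's moderated spread and drawn independently of the others. Unlike on the real arrays, no simulated array stood apart from its group and genes did not vary together. With 3 against 3 arrays it recovered 43% of 100 genes changed 2-fold and 91% of 100 changed 4-fold, with 13 false calls among 147. With transgenic replicate 3 left out, these shares were 48% and 97%. All of these shares describe the simulated genes only. In the real comparison Gdap10, Slc2a4 and Adipoq were lower by 7.48-fold, 7.8-fold and 5.42-fold and were not called (limma adjusted p = 0.428 each). The simulated shares therefore do not tell how many large changes the real comparison missed.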

Results

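Primary aortic endothelial cell cultures of mice carrying a dominant negative human PPARG (the V290M form, placed under the endothelial CDH5 promoter) and of non-transgenic mice were profiled on Affymetrix GeneChip mouse genome arrays. PPARG is a nuclear receptor that binds fatty acid ligands and switches on genes of lipid uptake and storage. Each culture came from 2 mice, 5 cultures were grown per group, and RNA of 3 cultures per group was put on 6 arrays, so that the replicates are separate cultures and n = 3 in each group. The median signal over all probe sets was 220.5, 219.9 and 222.9 on the non-transgenic arrays and 183.6, 186.1 and 173 on the transgenic arrays, while the trimmed mean to which the arrays were scaled was near 1500 on each. The number of arrays limits the precision of every value below. All differences are transgenic minus non-transgenic on the log2(signal + 16) scale, which understates the change of dim genes.

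The comparison asked which genes differ between cultures of transgenic and of non-transgenic mice. Whether the cells expressed the interfering receptor is not shown by these values. Lipid genes known as PPARG targets lay lower on average in the transgenic cultures, by a mean log2 difference of -0.76 over 21 genes, and cell cycle genes lay higher, by 1.28 over 30 genes. With an estimated correlation between genes neither list passed limma's camera (adjusted p = 0.583 for each). Transgenic replicate 3 lay inside the non-transgenic range on both, at -0.21 and -0.12 against the non-transgenic average. The target list includes genes of fat cells, such as Adipoq and Aqp7, so its mean may also vary with fat cells in the cultures, which was not tested. The genes with the smallest p among the higher ones were Csf1r, the receptor of macrophage colony stimulating factor, at 1.83 ± 0.26 (SE, n = 3 per group), and Masp1, a serine protease of the lectin pathway of complement, at 1.78 ± 0.27. Among the lower ones these were Kcnq1ot1, a long noncoding RNA of an imprinted region, at -1.46 ± 0.23 and Trp53inp1, a gene induced by p53, at -0.53 ± 0.10. No single gene passed the threshold. limma called 0 of 11208 genes at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.428. An unadjusted p under 0.05 was found for 1288 genes (725 higher and 563 lower), where chance gives 560 on average.

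The groups did not overlap for 1805 genes, which is 16.1% of those tested, against the 10% that chance gives on average for 3 against 3. Genes varied together across the arrays, so chance counts can lie far from their average. Other splits of the 6 arrays, 3 against 3, gave 50 to 1894 genes at an unadjusted p under 0.05, against 1288 in the real split. These excesses over the chance average therefore do not show a group effect. Transgenic replicate 3 stood apart from the other transgenic cultures. Its mean rank correlation across genes was 0.972 with the non-transgenic arrays and 0.907 with transgenic replicates 1 and 2, and on the first principal component, which held 65% of the variance, it lay at -30.2 beside the non-transgenic arrays at -15.9, -32.3 and -26.5, with transgenic replicates 1 and 2 at 38.4 and 66.6. Without this array limma called 1649 genes, 771 higher and 878 lower. With estimated array weights limma called 5504 genes, 2551 higher and 2953 lower, and that fit rested mostly on 1 array per group. Transgenic replicate 1 had a weight of 5.24 and non-transgenic replicate 2 one of 4.65, against 0.553 and 1.20 for non-transgenic replicates 1 and 3 and 0.349 and 0.177 for transgenic replicates 2 and 3. Of the 1649 genes, transgenic replicate 3 itself lay on the same side of the non-transgenic mean in 53.9%. Its median shift in the called direction was only 0.04, against a median difference of 1.16 in size without it. The 3' to 5' signal ratio of the Gapdh control probe sets, a measure of transcript length, was 1.59 ± 0.11 (SD, n = 3) in the non-transgenic and 1.33 ± 0.12 (SD, n = 3) in the transgenic group, with no overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). That of beta-actin was 2.00 ± 0.17 and 1.78 ± 0.41 (SD, n = 3 each, exact permutation p = 0.5).

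**Figure D1:**
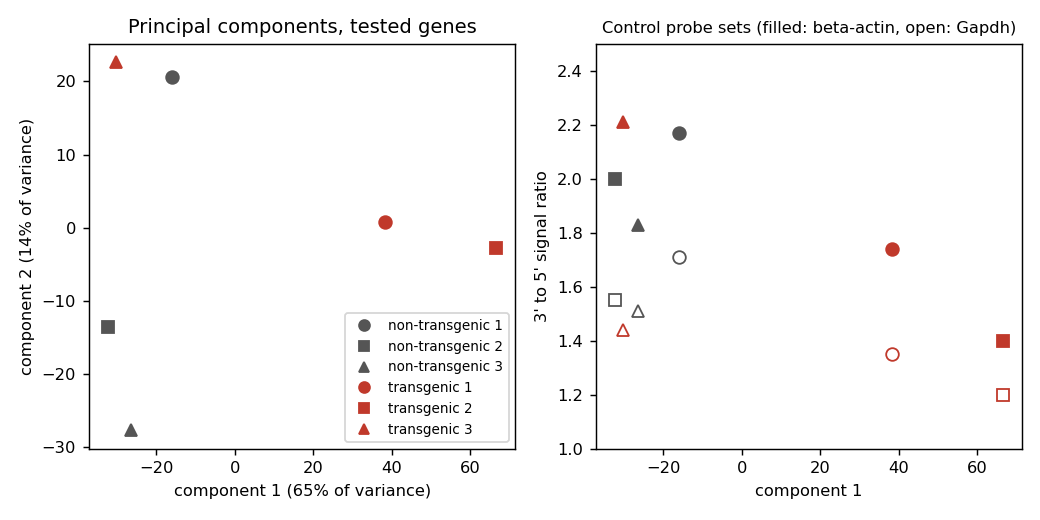
Left, the 6 arrays on the first and second principal components of the 11208 tested genes, with the share of variance on each axis; right, the 3' to 5' signal ratio (no unit) of the beta-actin and Gapdh control probe sets against the first component. Grey points are non-transgenic and red points transgenic cultures, with the marker shape giving the replicate; transgenic replicate 3 lies at -30.2 on the first component, among the non-transgenic arrays.

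Pparg itself, read by 1 probe set, was at 12.31, 11.37 and 10.57 in the non-transgenic cultures and at 11.57, 9.52 and 11.30 in the transgenic ones. The difference of -0.62 ± 0.61 (SE) was no larger than the spread between cultures (limma adjusted p = 0.681), and it was 0.02 without transgenic replicate 2, -0.17 without non-transgenic replicate 1, -1.04 without non-transgenic replicate 3 and -1.01 without transgenic replicate 1. It was 0.14 with array weights, -0.0139 with the beta-actin ratio as a covariate and 1.41 with the Gapdh ratio. The transgene is of human sequence, and whether the mouse probe set reads it is not known, so this gene does not check the labels. Fabp4, a fatty acid carrier of adipocytes and capillary endothelium and a direct PPARG target, was fixed for reporting in advance. Its brightest probe set differed by -0.40 ± 0.18 (SE, limma adjusted p = 0.437) and by 0.02 with array weights, and the next by -0.48 ± 0.21. The other 2 of its 4 probe sets, which were dimmer, differed by -1.94 ± 0.39 and -1.92 ± 0.33 (limma adjusted p = 0.205 for each when every probe set was tested), and on both all 3 transgenic cultures, replicate 3 included, lay below every non-transgenic culture. Rbp7, a retinol-binding protein of endothelium and fat, lay under the level filter at 7.14 and 7.18.

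**Figure D2:**
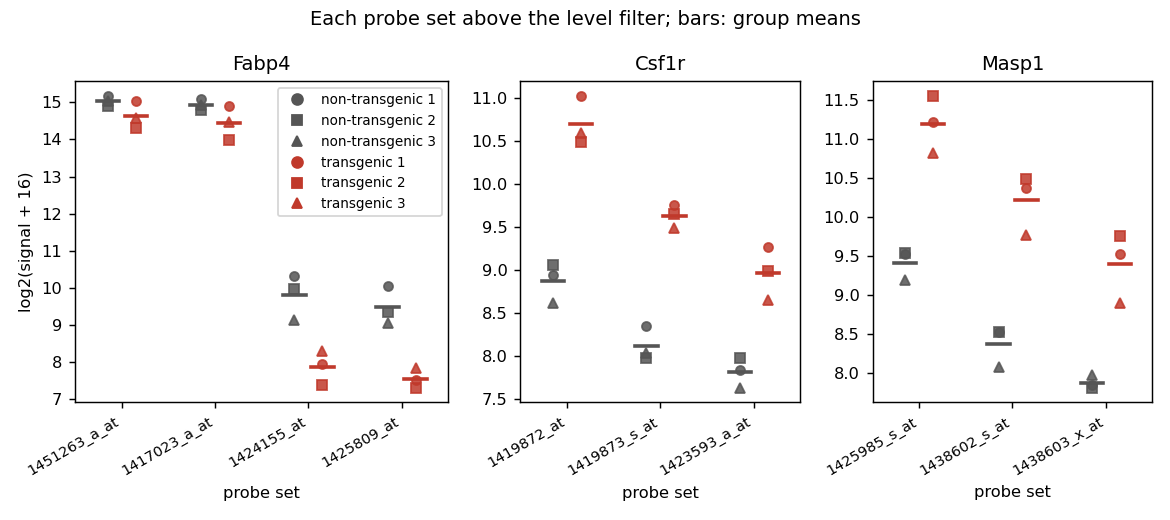
The log2(signal + 16) of each probe set above the level filter for Fabp4, Csf1r and Masp1 in every culture, with bars at the group means (n = 3 per group). Grey points are non-transgenic and red points transgenic. For Csf1r and Masp1, chosen by small p on these arrays, all 3 transgenic cultures lie above every non-transgenic one on each of 3 probe sets.

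Of the 10 genes with the smallest p among the higher ones, all had 3 transgenic cultures above every non-transgenic one. A choice by p on these same arrays favours such genes, so this is no separate support. Csf1r was at 8.94, 9.06 and 8.61 against 11.03, 10.49 and 10.59 on its brightest probe set, and all 3 of its probe sets lay higher. Masp1 was at 9.52, 9.54 and 9.19 against 11.22, 11.56 and 10.82, and its 3 probe sets above the level filter had the same direction. Hspb7, a small heat shock protein of muscle, differed by 1.24 ± 0.20 and Sphk1, which makes the signalling lipid sphingosine 1-phosphate, by 1.44 ± 0.27. The others were Ppp1r14b (0.95), the Ras effector Rin1 (1.29), the G protein subunit Gng8 (1.70), the apoptosis gene Siva1 (0.64), Sbsn (1.13) and the microtubule-binding protein Map6 (0.92). The 10 lower genes, chosen in the same way, all had 3 transgenic cultures below every non-transgenic one. Kcnq1ot1 was at 10.73, 11.10 and 10.97 against 9.43, 9.33 and 9.66. Gdap10 differed most, by -2.90 ± 0.63, from 10.85, 11.36 and 10.66 to 7.73, 6.88 and 9.55. Tet2, an enzyme that oxidises methylated cytosine, differed by -1.14 ± 0.24, and the Mediator subunit Med13 by -0.87 ± 0.18, although 1 of its 3 probe sets above the filter had the opposite sign. The rest were 2310067E19Rik (-1.52), Phxr4 (-1.13), Paip1, a partner of the poly(A)-binding protein (-1.06), the histone methyltransferase Prdm2 (-1.01) and Zhx1 (-0.87). Each of these 20 genes had a limma adjusted p of 0.428.

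Of 23 gene lists chosen in advance, 21 held at least 5 tested genes, and 7 passed an adjusted p of 0.05 in limma's camera with a preset correlation between genes, 5 of them higher and 2 lower. With a correlation estimated from the data 0 lists passed, with a smallest adjusted p = 0.583, and limma's fry called 0 lists in one direction. No gene of any list passed the threshold over all genes tested. Adjusted over the list alone, 1 gene passed, Csf1r among the leukocyte and macrophage markers, and 0 in each of the other lists. In 14 lists the means of transgenic replicates 1 and 2 both lay beyond those of the non-transgenic cultures on the same side. Replicate 3 lay there too in 2 of them, the NF-kappaB and the leukocyte list. On the leukocyte list, with 5 tested genes, it was at 0.408 against a highest non-transgenic value of 0.381. This rested mostly on Csf1r, also picked above by its small p, which was at 10.59 in replicate 3 against a non-transgenic mean of 8.87.

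Cell cycle genes lay higher in 30 of 30 tested, with a mean log2 difference of 1.28 (camera adjusted p = 9.09e-12, and adjusted p = 0.583 with an estimated correlation of 0.888 between the genes). The list mean relative to the non-transgenic average was 1.77 and 2.20 in transgenic replicates 1 and 2 and -0.12 in replicate 3, against 0.55, -0.23 and -0.33 in the non-transgenic cultures. It was 1.99 without transgenic replicate 3 and 0.83 without replicate 2. The replication helicase subunit Mcm2 differed by 1.40 ± 0.33 and the ribonucleotide reductase subunit Rrm1 by 1.02 ± 0.31. Cholesterol synthesis and uptake genes lay higher in 16 of 17, with a mean of 0.61 (camera adjusted p = 4.14e-05, and adjusted p = 0.583 with an estimated correlation). The mean was 0.37 without transgenic replicate 2. Mvd, which makes isopentenyl diphosphate, differed by 1.02 ± 0.34 and the sterol oxidase Msmo1 by 0.99 ± 0.35, the second of its 2 probe sets having the opposite sign. The Gapdh ratio did not overlap between the groups, and with it as a covariate their means were 0.33 and 0.29 and neither passed. With the beta-actin ratio they were 0.78 and 0.42 and both passed.

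PPARG target genes lay lower in 17 of 21, with a mean of -0.76 (camera adjusted p = 0.000509, and adjusted p = 0.583 with an estimated correlation). The list mean was 0.58, -0.15 and -0.43 in the non-transgenic cultures and -0.70, -1.36 and -0.21 in the transgenic ones, so that transgenic replicate 3 lay inside the non-transgenic range. It was -0.47 without non-transgenic replicate 1 and -0.45 without transgenic replicate 2. With the beta-actin ratio as a covariate it was -0.37 and passed. With array weights it was -0.59 and did not pass, and with the Gapdh ratio as a covariate it turned to 0.46 and did not pass. The redox regulator Txnip differed by -0.38 ± 0.12 and the glycerol channel Aqp7, a gene of fat cells, by -2.40 ± 0.76. Adipocyte markers, of which 2 tested genes are also on the target list, had a mean of -1.17 over 10 genes and did not pass (camera adjusted p = 0.102), with list means of 1.43, -0.46 and -0.97 in the non-transgenic and -0.99, -2.07 and -0.45 in the transgenic cultures. This list did pass without a filter (-1.11) and without non-transgenic replicate 2 (-1.40) or 3 (-1.65). Its mean was -0.45 without non-transgenic replicate 1 and -0.72 without transgenic replicate 2, and it passed in the opposite direction, at 1.04, with the Gapdh ratio as a covariate. The glucose transporter Slc2a4 differed by -2.96 ± 0.99 and the fat hormone Adipoq by -2.44 ± 0.996. Fatty acid oxidation genes had a mean of -0.20 over 21 genes (camera adjusted p = 0.102), led by Acadm at -0.95 ± 0.44 and Etfa at -0.28 ± 0.13. They passed with quantile normalization (-0.19) and without non-transgenic replicate 2 (-0.23), non-transgenic replicate 3 (-0.25) or transgenic replicate 1 (-0.24), while their mean was -0.10 without non-transgenic replicate 1 and -0.06 without transgenic replicate 2.

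**Figure D3:**
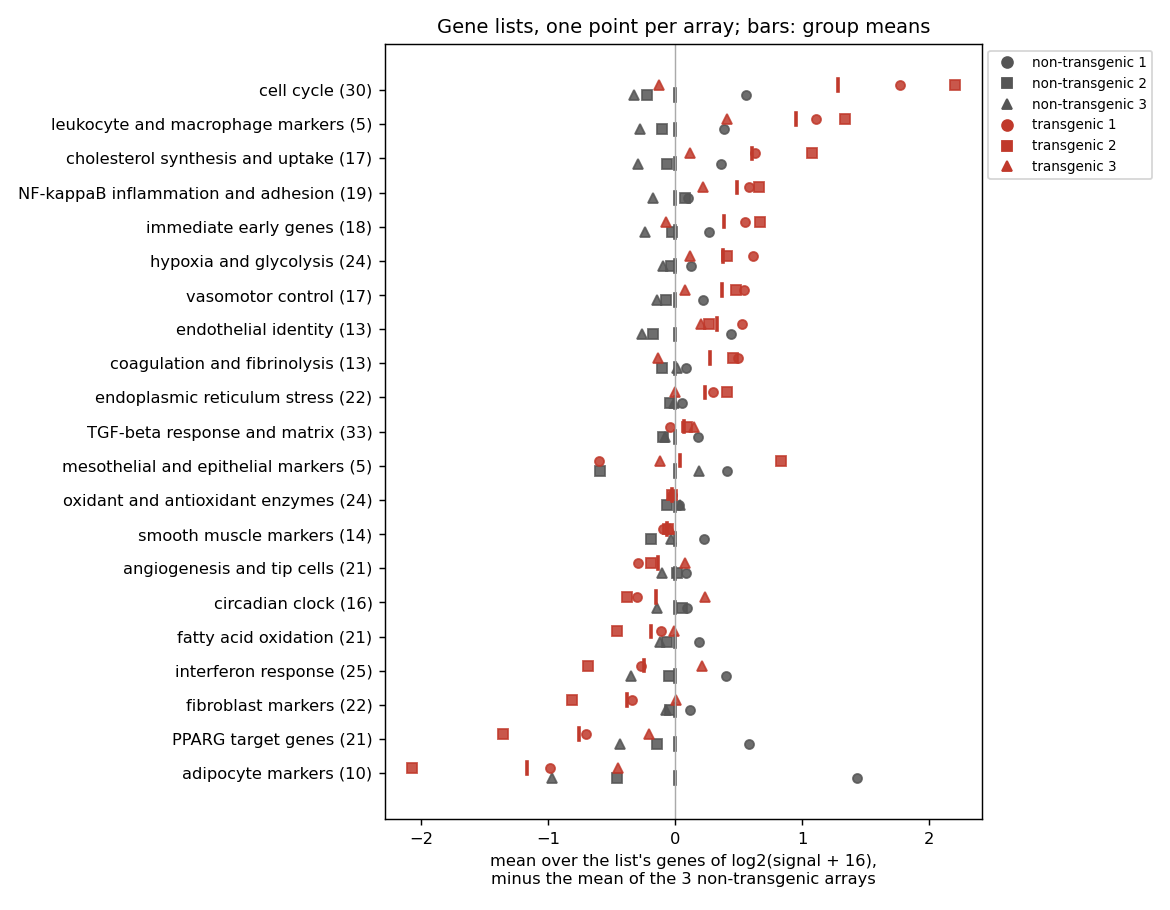
For each tested list (number of tested genes in brackets), the mean over its genes of log2(signal + 16) in every culture, minus the mean of the 3 non-transgenic cultures. Grey points are non-transgenic and red points transgenic cultures, shapes give the replicate and bars the group means; for the cell cycle list transgenic replicates 1 and 2 lie at 1.77 and 2.20 and replicate 3 at -0.12.

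Hypoxia and glycolysis genes lay higher in 20 of 24, with a mean of 0.38 (camera adjusted p = 0.00154, and adjusted p = 0.583 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, differed by 1.82 ± 0.59 and the phosphofructokinase Pfkl by 1.20 ± 0.34. The mean was 0.61 with array weights and 0.26 without transgenic replicate 1. In the transgenic cultures the list lay at 0.613, 0.405 and 0.116, replicate 3 being inside the non-transgenic range of -0.0928 to 0.123. NF-kappaB inflammation and adhesion genes lay higher in 14 of 19, with a mean of 0.49 (camera adjusted p = 0.0198, and adjusted p = 0.583 with an estimated correlation). The monocyte chemokine Ccl2 differed by 1.47 ± 0.46 and the neutrophil chemokine Cxcl5 by 2.34 ± 0.80. Both were highest in transgenic replicate 2, at 14.60 and 11.43, the culture with the most leukocyte and macrophage markers above the level filter (13 of 20 against 5 or 6 elsewhere). The 5 tested markers of that list had means of 1.11, 1.34 and 0.41 in the transgenic cultures, where the NF-kappaB list had 0.58, 0.66 and 0.22. This list did not pass with the filter at the 75th percentile (0.27) or with the mean of all probe sets per gene (0.43). Endoplasmic reticulum stress genes lay higher in 14 of 22, with a mean of 0.23 (camera adjusted p = 0.0219, and adjusted p = 0.583 with an estimated correlation). Asparagine synthetase, Asns, differed by 0.64 ± 0.15 and Creld2 by 0.62 ± 0.20. The list did not pass without non-transgenic replicate 1 (0.26), transgenic replicate 1 (0.20) or transgenic replicate 2 (0.15), and its mean was 0.35 without transgenic replicate 3 and 0.14 with the beta-actin ratio as a covariate, where it did not pass. With the Gapdh ratio as a covariate the means of these 3 lists were 0.34, 0.32 and 0.02, and none of the 3 passed.

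Fibroblast markers lay lower in 15 of 22, with a mean of -0.38 (camera adjusted p = 0.0302, and adjusted p = 0.583 with an estimated correlation). The actin-severing protein Gsn differed by -0.32 ± 0.10, while the surface glycoprotein Thy1 went the other way at 0.90 ± 0.26. The call was lost without non-transgenic replicate 1 (-0.32) and transgenic replicate 2 (-0.17), with the filter at the 75th percentile (-0.33), without the variance trend (-0.38), with array weights (-0.32), with the mean of all probe sets (-0.38) and with the beta-actin ratio as a covariate (-0.16). It was -0.58 without transgenic replicate 3 and 0.24 with the Gapdh ratio as a covariate. Leukocyte and macrophage markers had a mean of 0.95 over 5 tested genes (camera adjusted p = 0.102), with Csf1r at 1.83 and Cd53 at 2.54 ± 1.25. The list passed limma's mixed fry test of change in either direction (adjusted p = 0.0335), Csf1r being the 1 gene of the 5 with an unadjusted p under 0.05. Transgenic replicate 2 stood apart, with 13 of the 20 markers on the array above the level filter there against 5 or 6 on each other array, among them C1qb at 10.16, Ctss at 9.82 and Laptm5 at 9.22, named after their values were seen, against at most 8.83, 7.20 and 7.19 elsewhere. The list passed camera without a filter (0.49) and with every probe set on its own (0.89). Smooth muscle markers had a mean of -0.07 over 14 genes (camera adjusted p = 0.832), with Itga8 at -0.87 ± 0.37 and Actn1 at 0.51 ± 0.22. Mesothelial and epithelial markers had a mean of 0.04 over 5 genes (camera adjusted p = 0.92), with Wt1 at -0.79 ± 0.40 and Krt7 at 0.86 ± 0.44.

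Of 30 endothelial identity genes on the array, 13 lay above the level filter (43.3%), among them Cd34, Eng, Ramp2 and Flt1, the first 3 named after their values were seen. Cdh5, whose promoter drives the transgene, Pecam1 and Nos3 lay under it with group means of 6.97 and 6.09, 5.68 and 6.14, and 6.80 and 7.42. All 22 fibroblast markers lay above the filter, as did 14 of 20 smooth muscle, 10 of 12 adipocyte, 5 of 20 leukocyte and macrophage, 4 of 8 lymphatic endothelial, and 5 of 11 mesothelial and epithelial markers, against 61.6% of all genes. These counts use the mean over the 6 arrays. Array by array, leukocyte and macrophage markers above the filter numbered 6, 5 and 6 in the non-transgenic and 6, 13 and 5 in the transgenic cultures, and adipocyte markers 11, 10 and 10 against 8, 6 and 11. The endothelial and fibroblast shares differed (Fisher's exact p = 8.94e-06, over genes, which are not independent replicates). Against all other genes the fibroblast share was higher (Fisher's exact test, adjusted p = 0.000198 over 7 lists) and the leukocyte share lower by the mean over arrays (adjusted p = 0.0063), while that of the endothelial list did not pass (adjusted p = 0.136). Probe sets differ in how brightly they respond, so these shares are not amounts of RNA. The 13 tested endothelial genes had a mean difference of 0.33 (camera adjusted p = 0.0843), 9 of them lying higher and 4 lower. Those with the smallest p were the regulator of endothelial migration Ecscr, at 1.76 ± 0.71, and the VEGF receptor Flt1, at 1.01 ± 0.45. Ramp2 went the other way, at -1.74 ± 0.96. The list mean was 0.44, -0.17 and -0.26 in the non-transgenic cultures. It was 0.52, 0.27 and 0.20 in the transgenic ones, of which replicates 2 and 3 lay inside the non-transgenic range. The list passed with quantile normalization (0.48), with every probe set on its own (0.47) and without non-transgenic replicate 1 (0.55). Its mean was 0.20 without non-transgenic replicate 3 and ran from 0.13 without a filter to 0.64 with array weights.

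The lists of vessel function and of signalling responses did not pass at the chosen settings. Vasomotor control genes had a mean of 0.37 over 17 genes (camera adjusted p = 0.121), with prostacyclin synthase, Ptgis, at 0.42 ± 0.14 and Gch1, which makes the cofactor of nitric oxide synthase, at 1.56 ± 0.55. This list passed without a filter (0.45), with array weights (0.58), with every probe set on its own (0.53) and without transgenic replicate 3 (0.51). Its mean ran from 0.19 to 0.58 over the alternatives fixed in advance. Oxidant and antioxidant enzymes had a mean of -0.02 over 24 genes (camera adjusted p = 0.92), and of 0.00466 with median centring, with catalase, Cat, at -0.44 ± 0.13 and Gpx1 at 0.59 ± 0.19. Coagulation and fibrinolysis genes had a mean of 0.27 and a median of -0.03 over 13 genes (camera adjusted p = 0.506, direction higher), with the protease inhibitor Tfpi2 at 1.89 ± 0.59 and the urokinase receptor Plaur at 1.73 ± 0.75. Angiogenesis and tip cell genes had a mean of -0.14 over 21 genes (camera adjusted p = 0.506), with the VEGF co-receptor Nrp1 at -1.02 ± 0.25 and Angpt1 at -0.97 ± 0.31. TGF-beta response and matrix genes had a mean of 0.07 over 33 genes (camera adjusted p = 0.834), with Ltbp2 at 1.67 ± 0.46 and Timp1 at 0.53 ± 0.18. Interferon response genes lay lower in 20 of 25, with a mean of -0.25 (camera adjusted p = 0.075), Ifit2 being at -0.58 ± 0.22 and the immunoproteasome subunit Psmb9 at -0.82 ± 0.36. They passed with median centring (-0.22) and without non-transgenic replicate 2 (-0.27), non-transgenic replicate 3 (-0.42) or transgenic replicate 3 (-0.48). Their mean was -0.05 without non-transgenic replicate 1 and -0.03 without transgenic replicate 2, and they passed in the opposite direction, at 0.66, with the Gapdh ratio as a covariate. Circadian clock genes had a mean of -0.15 over 16 genes (camera adjusted p = 0.297), with Bhlhe40 at 1.81 ± 0.58 and Nr1d2 at -0.76 ± 0.37. Immediate early genes had a mean of 0.38 and a median of -0.02 over 18 genes (camera adjusted p = 0.57, direction higher), with Ier3 at 1.19 ± 0.29 and Maff at 1.16 ± 0.39. Single transgenic cultures moved several of these means. Without transgenic replicate 1, 2 or 3 in turn, the coagulation mean was 0.16, 0.18 and 0.47 and the circadian mean -0.07, -0.03 and -0.34. The angiogenesis mean was -0.05 without transgenic replicate 1 and -0.24 without replicate 3, and the immediate early mean 0.24 without replicate 2 and 0.61 without replicate 3. The TGF-beta mean ran from 0.02 to 0.16 over the arrays left out.

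On each of the 6 arrays Xist, expressed from the inactive X chromosome of females, lay under the level filter, at group means of 6.54 and 5.87, while the Y-linked genes Eif2s3y (12.77 and 12.30), Kdm5d (11.05 and 10.94) and Uty (9.40 and 8.99) lay above it. Their differences were -0.46, -0.11 and -0.41, and that of Kdm5d was 0.20 with array weights.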

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

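The fits with a 3' to 5' ratio as a covariate were chosen only after the result was seen, and all other alternatives were fixed in advance. limma called 0 genes under each alternative except 2. Without transgenic replicate 3 it called 1649 (771 higher, 878 lower), and with array weights 5504 (2551 higher, 2953 lower). The leave-one-out ranges were 0 to 1649 genes, 0 to 771 higher, 0 to 878 lower, 426 to 3643 genes at an unadjusted p under 0.05 (1288 with all arrays), 5 to 10 lists, and -1.04 to 0.0177 for Pparg. The unadjusted count was 426 without non-transgenic replicate 2, 532 without non-transgenic replicate 3, 639 and 734 without transgenic replicates 1 and 2, and 3643 without transgenic replicate 3. It was 856 with the filter at the 75th percentile, where fewer genes were tested, 3602 of 22519 with every probe set on its own, 6354 with array weights and 763 with the Gapdh ratio as a covariate. The count of lists past the threshold, 7, was 0 with an estimated correlation, 0 with fry, 2 with the Gapdh ratio and 5 to 10 elsewhere. None of the 7 passed with the Gapdh ratio, and the 2 that did, interferon response and adipocyte markers, passed with their signs turned. The deviations of same-numbered arrays from their group means correlated at 0.042, -0.28 and -0.034, which gave no sign that the replicate numbers pair the samples. Deviations from means of 3 arrays are too few to exclude a pairing. With the replicate number as a block 0 genes and 8 lists passed, adipocyte markers among them at -1.17, 1117 genes had an unadjusted p under 0.05 and Pparg stood at -0.62.

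Signs turned as follows, and the cause was not tested. With array weights these were Pparg 0.14, Fabp4 0.0153, Kdm5d 0.20, and the lists of mesothelial and epithelial markers -0.14, oxidant enzymes 0.00898 and smooth muscle markers 0.0297. With the Gapdh ratio, Pparg was at 1.41, Acadm 0.43, Adipoq 1.24, Aqp7 0.0465, Cxcl5 -0.047, Flt1 -0.38, Itga8 0.15, Plaur -0.23, Psmb9 0.10, Slc2a4 0.60 and Wt1 0.24. The lists were then at 0.46 (PPARG targets), 1.04 (adipocyte), 0.0874 (angiogenesis), 0.30 (circadian), -0.0121 (coagulation), 0.25 (fatty acid oxidation), 0.24 (fibroblast), 0.66 (interferon), -0.44 (mesothelial and epithelial) and 0.0938 (smooth muscle). With the beta-actin ratio the circadian list was at 0.0297, interferon at 0.0504 and mesothelial and epithelial at -0.18. The last was at -0.14 with every probe set on its own and -0.15 without a filter. Without a filter the oxidant list was at 0.00804 and smooth muscle at 0.20, and with median centring the oxidant list was at 0.00466. Leaving out 1 array gave -0.45 to 0.11 for Kdm5d, -0.36 to 0.36 for the mesothelial and -0.163 to 0.0447 for the smooth muscle list. Quantile normalization and median centring put the median of all genes at 0.01 and 0.01, against -0.02. MAS5 signals near background have little precision, which limits the genes under the filter most.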

Other observations

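The gene families in the first 2 paragraphs and the tests in the others were chosen only after the result was seen, except the splits for the list count, the shares on the side of transgenic replicates 1 and 2, and the count of endothelial probe sets.

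Zinc finger genes (symbols starting with Zfp) lay lower in 234 of 285 tested, with a mean log2 difference of -0.31 (camera adjusted p = 2.73e-07 over 21 families, and adjusted p = 0.803 with an estimated correlation). Their means relative to the non-transgenic average were -0.32, -0.51 and -0.10 in the transgenic cultures and -0.16, 0.13 and 0.02 in the non-transgenic ones. Genes of the mitochondrial ribosome lay higher in 63 of 76, by a mean of 0.19 (camera adjusted p = 9.21e-06, and adjusted p = 0.803 with an estimated correlation), at 0.26, 0.22 and 0.08 against 0.04, -0.06 and 0.03. Here transgenic replicate 3 lay on the side of the other transgenic cultures.

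Genes annotated as long noncoding RNA lay lower in 194 of 286, by a mean of -0.24 (camera adjusted p = 0.00247, and adjusted p = 0.803 with an estimated correlation), and by -0.10 with quantile normalization. Lysine demethylases were at -0.30 over 17 genes and Wnt and frizzled genes at -0.33 over 12 (camera adjusted p = 0.026 and 0.0441, and adjusted p = 0.803 for both with an estimated correlation). Nucleoporins were at 0.17 over 17 genes and proteasome genes at 0.09 over 38 (camera adjusted p = 0.0496 and 0.0441, and adjusted p = 0.803 and 0.818 with an estimated correlation). Transgenic replicate 3 lay inside the non-transgenic range for the demethylases (-0.037, range -0.10 to 0.087) and the proteasome (0.0046, range -0.12 to 0.13), and for the Wnt and frizzled genes it lay opposite to the family mean, at 0.081 against at most 0.079. For the long noncoding RNAs (-0.10, lowest non-transgenic -0.062) and nucleoporins (0.12, highest 0.056) it lay beyond them on the side of the other transgenic cultures. The sign of each of these 7 means was the same with quantile normalization and with median centring. In all, 7 of 21 families passed at the preset correlation and 0 with an estimated one.

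The 6 arrays can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split called 0 genes and the highest of the others 6, and no split can call fewer than 0. At an unadjusted p under 0.05 the real split gave 1288 genes and the highest other 1894, with 3 of 10 as large, and both other splits with more genes kept transgenic replicates 1 and 2 in one arm. For gene lists these were 7 and 10, with 5 of 10 as large.

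Transgenic replicate 3 lay with the non-transgenic arrays. A swap with one of these would leave a non-transgenic array out of place, and 0 of the 3 correlated better with transgenic replicates 1 and 2, which argues against it. A non-transgenic culture under a transgenic label stays open as a candidate explanation: where transgenic replicates 1 and 2 lay beyond the 3 non-transgenic arrays, replicate 3 did so on their side in 32.1% of genes, inside the 14.4% to 43% that each non-transgenic array gave when put in its place. It did lie with them on 2 probe sets of Fabp4, on Csf1r and on Masp1, which were picked after their values were seen. RNA integrity or amplification stays open too, since its beta-actin ratio of 2.21 lay just above those of the non-transgenic arrays (1.83 to 2.17) while its Gapdh ratio of 1.44 lay below all of them (1.51 to 1.71), and a transgene effect that differs between cultures was not tested. The median signal of replicate 3, 173, lay with those of transgenic replicates 1 and 2 (183.6 and 186.1), below the non-transgenic arrays (219.9 to 222.9). The median signal and the Gapdh ratio did not overlap between the groups. A processing difference that follows the groups cannot be told apart from the transgene in this design.

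The cell cycle list lay higher and the PPARG target list lower. RNA integrity or amplification may account for part of this. With the beta-actin ratio as a covariate the cell cycle mean went from 1.28 ± 0.77 (SE of the list mean over arrays) to 0.776 ± 0.69 and the PPARG mean from -0.76 ± 0.45 to -0.37 ± 0.23, both still past camera's threshold at the preset correlation, but within their spread of losing most of the difference, and neither list passed without the covariate when the correlation was estimated (adjusted p = 0.583 for each). With the Gapdh ratio the cell cycle mean was 0.325 ± 1.33 and the call ended, with an SE too large to tell a lost from a kept difference, while the PPARG mean turned to 0.46 ± 0.12 and did not pass camera. On the PPARG target list non-transgenic replicate 1 was highest, at 0.58, and transgenic replicate 2 lowest, at -1.36. On the adipocyte list, which shares 2 tested genes with it, the same arrays were highest and lowest, at 1.43 and -2.07. The target list also holds genes of fat cells that are not on the adipocyte list, such as Aqp7. The lists are therefore not independent, and the target list mean cannot be read apart from fat cells in the cultures. Cells of another type in the cultures stay open for the PPARG difference and were not tested as its cause. An effect of the transgene remains open and was not tested apart from RNA integrity, amplification or other cells.

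Of the endothelial list 17 of 30 genes lay under the level filter, a share that did not pass against other genes (adjusted p = 0.136, Fisher's exact test), and all 22 fibroblast genes lay above it. Cells of another type in the cultures stay open. The share of the fibroblast list above the filter, at least 95.5% on every array, cannot decide, since it follows from the pattern itself. The levels of different probe sets are not amounts of RNA. Leukocyte and macrophage markers above the filter numbered 6, 5 and 6 in the non-transgenic and 6, 13 and 5 in the transgenic cultures. Why transgenic replicate 2 had more was not tested. Among all genes on the array, the median percentile of mean level was 35 for the endothelial and 95 for the fibroblast list. Cdh5, Pecam1 and Nos3, fixed for reporting in advance, lay at percentiles 27, 18 and 33. The values therefore do not show that the cultures were mainly endothelial. How many of these 22 fibroblast genes cultured aortic endothelial cells also express is not known here, and no sort or gate is described in the labels. Endothelial probe sets that respond poorly stay open, since 6 of the 17 endothelial genes under the filter had 2 or more probe sets with none above it and the other 11 had 1 each. No biological explanation was tested.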
